A study of Mus musculus with 6 samples.

How the data were processed

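The series holds 6 mRNA sequencing libraries of mouse Treg cells differentiated in culture, 3 labelled WT and 3 labelled Ifnar1-SA, from RNA extracted with a miRNeasy kit, per the labels' protocols. The authors deposited 1 table of gene-level TPM, a length-corrected share of transcripts, with 24493 gene symbols and 6 columns, and each column name matched the title of 1 sample. Quantification was done with Salmon on the mouse builds mm10 and GRCm38, per the submitters' processing notes. The Salmon version, the annotation, the way transcripts were combined to genes and any read filter are not given in the sources used here.

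TPM corrects for transcript length and scales every library to 1e+06, so the number of reads behind a value is unknown and no counting interval could be given. A gene that takes a large share of a library lowers the TPM of all others, and very short transcripts reach several TPM from few fragments. A value of 0 can be a failed estimate, so genes listed at 0 throughout a genotype are given as each library's value and without a fold.

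Values were tested as log2(TPM + 1) for the 12141 genes with a mean of at least 1 TPM over the 6 libraries. Fold changes on this scale understate the change of low genes. The main test was limma with an intensity trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, without a replicate block. No count model was used, since the table holds no counts. For single values, list means and genes under the filter, exact two-sided permutation tests were used, for which 3 against 3 libraries cannot go below 0.1.

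Before the data were examined, 33 gene lists with 716 symbols were fixed, of which 19 symbols were not found in the table by that name. The 30 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the 30 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, so medians are given relative to that of all genes tested. Of the 13 lists past the threshold at the preset correlation, 0 passed with an estimated correlation (lowest adjusted p 0.505) and 0 with fry (lowest adjusted p 0.485, or 0.101 for a change in either direction). P-values adjusted over the list alone used the members of that list only. This adjustment was not among the tests fixed before the data were examined. It does not correct across the 30 lists, and it is lenient for lists with few members. The mitochondrially encoded, erythroid and platelet, and stromal and endothelial lists had fewer than 3 measured members and were not tested.

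The rule for named genes, also fixed before the data were examined, took Ifnar1, Ifnar2, Foxp3 and the interferon genes. It added up to 12 genes per direction past the threshold without overlap between the genotypes, filled to 6 per direction by smallest p, and predicted gene models were left out. From each list it took up to 4 members past the threshold or, where there was none, the 2 members of smallest p. All other genes named were chosen after their values were seen: the further interferon-stimulated genes, Ctla4, Tigit among the Treg genes, Dusp4, Il2ra, Ikzf2, Itgae, Lrrc32, Il4, Il13, Gata3, Tbx21, Tcf7, Lyz2, H2-Ab1, Ddx3y, Rn4.5s, Rps29, Mir6236 and those of the closing part. Positions are from the GENCODE M21 annotation of GRCm38, matched by symbol.

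Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 TPM, median-of-ratios, TMM (trimmed mean of M-values) and quantile scaling, no intensity trend, robust empirical Bayes, array weights, leaving out mitochondrially encoded and ribosomal protein genes (the table had none of the former, so only the latter were left out), a replicate block, and leaving out each library in turn. Others chosen after seeing the data were leaving out small RNA genes, a model term for WT 2 and Ifnar1-SA 1, and leaving out both of these libraries. The procedure was tested on simulated data for this comparison, with 12141 genes of which 200 were changed in each of 10 runs. It recovered 45.2% of 2-fold and 95.6% of 4-fold changes, with 6.52% false among the calls. A list shifted by 0.6 on the log2 scale was found in 10 of 10 runs by camera, camera with an estimated correlation and fry. Simulated genes varied independently, with normally distributed log2 values, and the changed genes had a mean log2(TPM + 1) above 2. These rates therefore do not describe genes whose values rest on a few fragments or are 0 throughout a genotype. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and figures.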

Results

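Messenger RNA was sequenced from mouse cells labelled as regulatory T (Treg) cells, after naive CD4 T cells of the spleen had been differentiated in culture. Treg cells are the CD4 T cells that restrain immune responses. The 6 libraries fell into 2 genotypes, with 3 wild-type (WT) and 3 Ifnar1-SA libraries. Ifnar1 encodes a chain of the type I interferon receptor, and in published work the SA name stands for a knock-in allele in which a serine of the receptor's degradation signal is replaced by alanine, which leaves the receptor resistant to degradation. The comparison asked how the transcriptome of these cells differed between the genotypes. Expression was given as TPM, a length-corrected share of transcripts that sums to 1e+06 in each library and keeps no sequencing depth. Of 24493 gene symbols, between 21925 and 22958 were above 0 in a library. Pearson's r of log2 values across genes, which are not independent replicates, was 0.944 to 0.961 within a genotype and 0.939 to 0.966 between genotypes, and 0 pairs of libraries held identical values. Values are given as mean ± SD over 3 libraries per genotype, and folds are ratios of mean TPM. The labels do not say whether the libraries of a genotype came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. For WT 3 the Y-linked genes argue against a purely technical spread. Eif2s3y was at 0 TPM there and at 17.0 and 16.8 TPM in WT 1 and WT 2, and Ddx3y differed likewise.

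Transcripts of the receptor itself did not pass the test between the genotypes. Ifnar1 (GRCm38 chromosome 16, 91485238 to 91507441, plus strand, protein-coding) was at 24.01, 41.9 and 27.3 TPM in the WT libraries and at 28.0, 25.3 and 21.8 TPM in the Ifnar1-SA libraries. The log2 difference was −0.27 with a standard error of 0.23 (limma, adjusted p = 0.9997). Ifnar2, the other receptor chain (chromosome 16, 91372783 to 91405589), was at 79.3 ± 20.6 TPM in WT and 64.0 ± 11.3 TPM in Ifnar1-SA (adjusted p = 0.9997). An amino acid replacement leaves no mark in gene-level TPM, so these values do not check the genotype labels. The 20 type I and type III interferon genes in the table were at most 1.75 TPM in any library, and 21 of their 120 values were 0. Ifnb1 (chromosome 4, 88522025 to 88522774) was at 1.16 ± 0.582 TPM in WT and 1.10 ± 0.468 TPM in Ifnar1-SA. Ifng, the type II interferon made by activated T cells (chromosome 10, 118441046 to 118445892), was at 28.7, 6.80 and 7.54 TPM in WT and 8.54, 22.95 and 28.6 TPM in Ifnar1-SA (adjusted p = 0.9997). Among 23 genes that act close to the receptor, 0 passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.984). Usp18, which restrains receptor signalling, was at 26.7 ± 17.9 TPM in WT and 68.2 ± 34.7 TPM in Ifnar1-SA, and Stat4, a signal transducer of interleukin-12, was at 13.4 ± 0.755 and 8.83 ± 2.68 TPM.

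Type I interferon-stimulated genes were higher in Ifnar1-SA as a list. Of the 49 measured members 48 had a higher mean log2 value, with a median log2 fold change 0.66 above that of all genes (camera adjusted p = 7.9e-48, adjusted p = 0.505 with an estimated correlation). When adjusted over the list alone, a test not fixed beforehand, 21 members rose and 0 fell. Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481, minus strand), was at 2.01, 3.44 and 2.94 TPM in WT against 28.1, 11.5 and 42.2 TPM in Ifnar1-SA, a 9.74-fold rise. Ifi27l2a (chromosome 12, 103442167 to 103443680), a classical interferon target, was at 267 ± 44.6 TPM in WT and 992 ± 425 TPM in Ifnar1-SA, a 3.71-fold rise. Both had an adjusted p of 0.0122 over the list alone, and 0.244 and 0.275 over all genes. Isg15, a ubiquitin-like modifier, went from 10.4 ± 1.07 to 55.1 ± 41.6 TPM, with 9.82 to 11.7 TPM in the WT libraries and 25.6 to 103 TPM in the Ifnar1-SA libraries. Bst2, which tethers budding virus to the cell surface, rose 2.10-fold from 246 ± 29.6 to 517 ± 144 TPM, and Xaf1, a gene linked to apoptosis, rose 3.48-fold from 15.5 ± 3.26 to 54.1 ± 24.3 TPM. Ly6a, which encodes the Sca-1 surface antigen, rose 1.55-fold from a WT level of 6843 ± 1385 TPM. The other members that rose over the list alone were Isg20, Oas3, Ifi44, Cmpk2, Zbp1, Trim30a, Parp14, Herc6, Slfn1, Sp100, Lgals3bp, Phf11b, Epsti1, Helz2 and Uba7. Several classical targets stayed near the floor in both genotypes. Ifit1 was at 0.822 ± 0.351 TPM in WT and 0.955 ± 0.244 TPM in Ifnar1-SA, and Ifit3 was at 0.540 ± 0.483 and 0.460 ± 0.134 TPM.

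Over all 12141 genes tested with limma, 0 of the interferon-stimulated genes passed an adjusted p of 0.05, while 28 had an unadjusted p under 0.05. The 3 WT libraries had list means of 3.73, 4.01 and 3.82 on the log2 scale and the Ifnar1-SA libraries 4.65, 4.20 and 4.90, without overlap. The exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries allow. List means of the CD8 T and NK cell markers (5.03 to 5.21 in WT, 5.49 to 5.61 in Ifnar1-SA) and of the neutrophil and mast cell markers (1.81 to 2.30 and 2.33 to 2.51) also did not overlap, each with that p. The count of 21 was 9 without WT 1, 4 without WT 3, 5 without Ifnar1-SA 1, 33 without Ifnar1-SA 2 and 5 without Ifnar1-SA 3. It was 0 when WT 2 and Ifnar1-SA 1 were left out together, a pair whose levels of some short transcripts stood apart from the other libraries, 12 with no filter on low values, 13 with array weights and 7 with a replicate block. Leaving out that pair, which leaves 2 libraries per genotype, took Irf7, Ifi27l2a, Isg15, Bst2 and Xaf1 to an adjusted p of 0.133 over the list alone. Their log2 fold changes were then 2.75, 1.88, 2.17, 1.11 and 1.60, against 2.74, 1.82, 2.05, 1.04 and 1.67 with all 6. Without WT 3 it was 0.0628 for Isg15, 0.0785 for Bst2 and 0.0925 for Ly6a, and without Ifnar1-SA 1 it was 0.0543 for Isg15 and Bst2 and 0.0932 for Ly6a. It was also 0.0598 for Isg15 without WT 1, 0.0657 for Ly6a without WT 2, and 0.0508 for Bst2 and 0.1304 for Ly6a without Ifnar1-SA 3. For Ly6a it was 0.153 without the pair, 0.116 with no filter on low values and 0.0779 and 0.0650 with median-of-ratios and TMM scaling. With a replicate block it was 0.0752 for Ly6a and 0.0534 for Bst2. Over all genes Irf7 passed without Ifnar1-SA 2 (adjusted p = 0.0231).

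**Figure D1:**
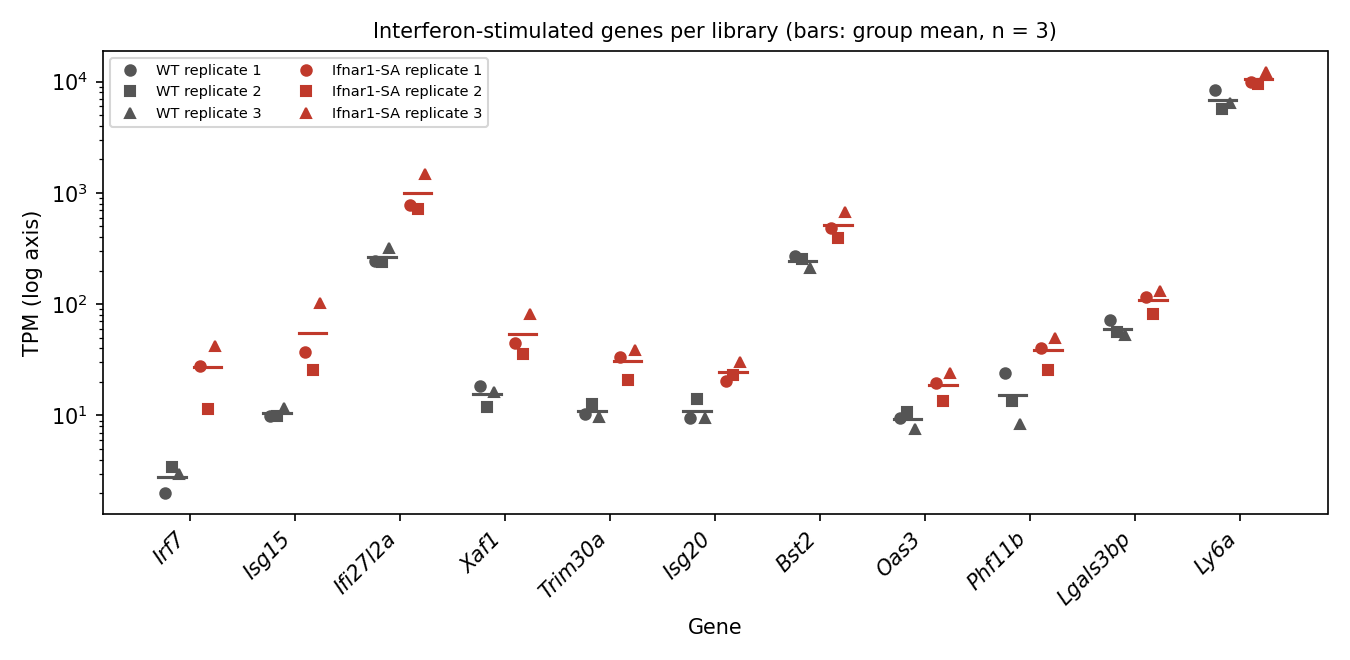
TPM of interferon-stimulated genes on a log axis, one column per gene, with a point for each of the 3 WT (grey) and 3 Ifnar1-SA (red) libraries and a bar at the mean of each genotype. The Irf7 points of Ifnar1-SA lie between 11.5 and 42.2 TPM, above all 3 WT points, which lie between 2.01 and 3.44 TPM.

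Genes of the neighbouring interferon and antigen presentation programmes were also higher in Ifnar1-SA as lists, by smaller amounts. The 21 measured interferon-gamma and GTPase genes had a median log2 fold change 0.24 above all genes (camera adjusted p = 6.3e-05, adjusted p = 0.606 with an estimated correlation), and 0 passed adjusted over the list alone. That median was 0.40 without Ifnar1-SA 2 and 0.15 without Ifnar1-SA 3 (adjusted p = 0.0353), and list means overlapped, at 3.79 to 3.94 on the log2 scale in WT and 3.75 to 4.30 in Ifnar1-SA. Irgm1, an immunity-related GTPase, was at 60.7 ± 3.71 TPM in WT and 99.8 ± 24.6 TPM in Ifnar1-SA. Tgtp1, another such GTPase, was at 12.7 ± 6.59 and 27.7 ± 9.63 TPM. The 24 genes of MHC class I presentation had a median 0.22 above all genes, with 20 of 24 higher in mean log2 value (camera adjusted p = 1.1e-05, adjusted p = 0.606 with an estimated correlation). Over the list alone 0 passed. The median was 0.11 without WT 2 and without Ifnar1-SA 3 (adjusted p = 0.0141 and 0.0457) and 0.12 with quantile scaling, and list means overlapped, at 7.62 to 7.77 in WT and 7.66 to 7.93 in Ifnar1-SA. H2-T22, a non-classical class I gene, was at 35.0 ± 1.77 TPM in WT and 49.0 ± 9.41 TPM in Ifnar1-SA, and the proteasome activator gene Psme2 was at 639 ± 50.8 and 858 ± 136 TPM.

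The list of Treg identity and suppression genes was higher in Ifnar1-SA, with mixed members, while Foxp3 itself was too low to be tested with the list. Its 35 measured genes had a median log2 fold change 0.19 above all genes (camera adjusted p = 2.5e-04, adjusted p = 0.606 with an estimated correlation). By mean log2 value 21 were higher and 14 lower, and 0 passed adjusted over the list alone. List means overlapped, at 5.73 to 5.85 on the log2 scale in WT and 5.82 to 6.01 in Ifnar1-SA. Il10, an anti-inflammatory cytokine, was at 189 ± 47.5 TPM in WT and 306 ± 45.1 TPM in Ifnar1-SA. The inhibitory receptors Lag3 (25.5 ± 1.39 and 37.2 ± 4.31 TPM), Tigit (86.2 ± 10.8 and 119 ± 11.9 TPM) and Ctla4 (575 ± 111 and 805 ± 61.7 TPM) had non-overlapping libraries. The phosphatase gene Dusp4 was at 37.1 ± 5.97 TPM in WT and 25.4 ± 4.63 TPM in Ifnar1-SA. Foxp3, the lineage-defining transcription factor of Treg cells (chromosome X, 7573644 to 7595245, plus strand), was under the expression filter. It was at 0.697, 0.295 and 0.276 TPM in WT and 0.746, 1.82 and 0.759 TPM in Ifnar1-SA (exact two-sided permutation p = 0.1, the smallest possible). Il2ra, the high-affinity interleukin-2 receptor chain, was at 390 ± 34.8 TPM in WT and 437 ± 12.7 TPM in Ifnar1-SA, while Ikzf2, Itgae and Lrrc32, other genes associated with Treg cells, were at most 2.73 TPM in any library. The median of the list was 0.15 above all genes at its lowest under the other scalings.

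Transcripts of several helper lineages were abundant in both genotypes. Il4, Il5 and Il13, the cytokines of type 2 helper (Th2) cells, were at 302 ± 67.0, 422 ± 124 and 116 ± 90.6 TPM in WT and 440 ± 183, 548 ± 40.3 and 163 ± 55.4 TPM in Ifnar1-SA. Gata3, the Th2 transcription factor, was at 143 ± 4.72 and 148 ± 12.9 TPM. Of the 12 Th2 genes 0 passed over the list alone and the list did not pass (camera adjusted p = 0.421). Il9 was at 63.6, 99.5 and 287 TPM in WT and 23.03, 11.7 and 43.0 TPM in Ifnar1-SA, which did not pass over the list alone (adjusted p = 0.0892). The 15 measured Th1 genes had a median 0.36 above all genes (camera adjusted p = 0.00871, adjusted p = 0.606 with an estimated correlation). The chemokine Ccl5 was at 42.2 ± 16.4 TPM in WT and 94.1 ± 43.5 TPM in Ifnar1-SA, and the Th1 transcription factor Tbx21 at 26.8 ± 10.4 and 32.1 ± 5.53 TPM. The Th1 call ended without WT 2 (adjusted p = 0.611) or Ifnar1-SA 3 (0.191) and with both of WT 2 and Ifnar1-SA 1 left out (0.0641). It also ended with median-of-ratios (0.125), TMM (0.180) or quantile (0.0840) scaling. The Th1 median was 0.66 above all genes without WT 1, 0.17 without WT 2, 0.24 without WT 3, 0.21 without that pair and 0.20 with no filter on low values, and list means overlapped between the genotypes. The 8 measured Th17 genes (camera adjusted p = 0.383) and 8 measured follicular helper genes (camera adjusted p = 0.421) did not pass. Among them Il6ra was at 4.45 ± 0.921 TPM in WT and 3.52 ± 1.04 TPM in Ifnar1-SA. Slamf6, a T cell surface receptor gene, was at 2.43 ± 1.27 and 0.808 ± 0.341 TPM and Cd200 at 203 ± 21.4 and 149 ± 32.7 TPM.

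**Figure D2:**
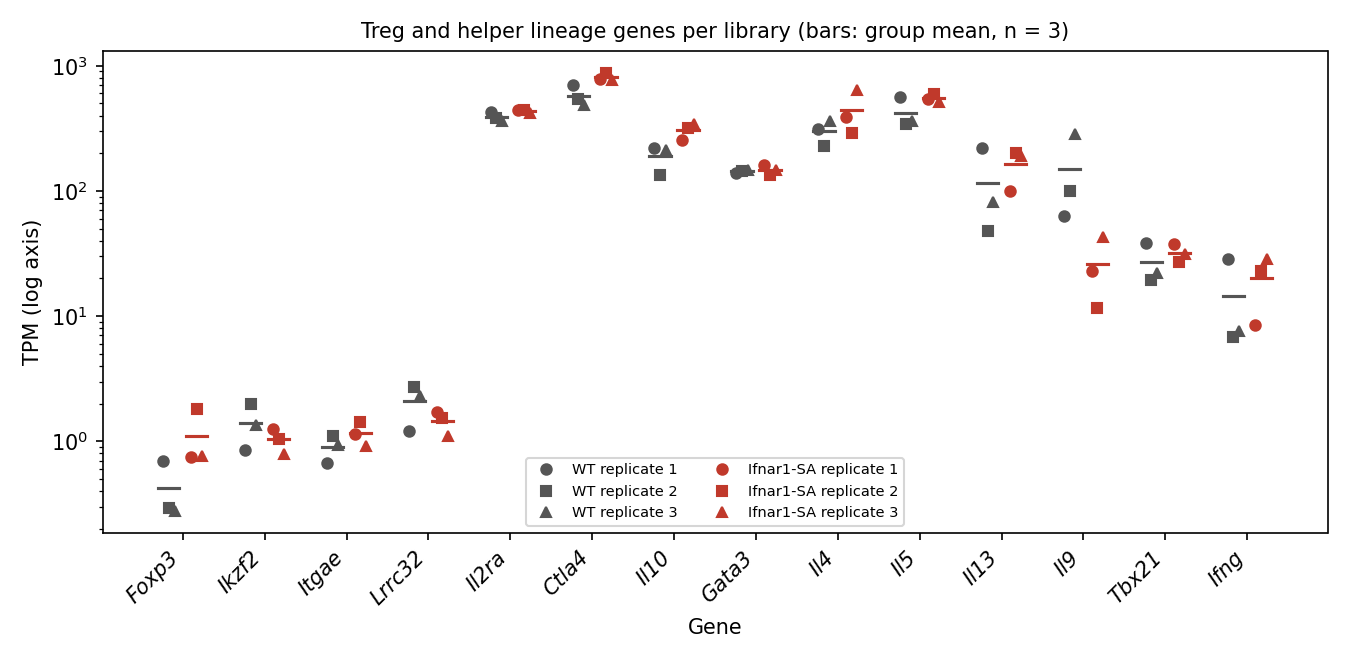
TPM of Treg and helper lineage genes on a log axis, one column per gene, with a point for each of the 3 WT (grey) and 3 Ifnar1-SA (red) libraries and a bar at the mean of each genotype. Foxp3 lies between 0.276 and 1.82 TPM, while Il4 and Il5 lie between 230 and 644 TPM in all 6 libraries.

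Genes of naive and memory T cells were lower in Ifnar1-SA as a list. The median log2 fold change was −0.34 relative to all genes, with 14 of 15 members lower in mean log2 value (camera adjusted p = 1.6e-04, adjusted p = 0.606 with an estimated correlation). It was −0.22 without WT 3, and list means overlapped, at 4.05 to 4.70 on the log2 scale in WT and 3.70 to 4.22 in Ifnar1-SA. Igfbp4, a growth factor binding protein gene expressed in naive T cells (chromosome 11, 99041244 to 99054392), was the 1 member that fell over the list alone, from 28.1 ± 8.16 to 8.79 ± 3.38 TPM (adjusted p = 0.0146). Its adjusted p was 0.0678 without Ifnar1-SA 2 and 0.0575 without Ifnar1-SA 3, and 0.0775 with a replicate block. Over all genes its adjusted p was 0.409 in the main limma test. It was 0.0407 with a model term for WT 2 and Ifnar1-SA 1, a setting chosen after seeing the data. Tcf7, a transcription factor of naive and memory T cells, was at 14.4 ± 3.68 TPM in WT and 7.85 ± 2.84 TPM in Ifnar1-SA. The 14 measured inhibitory receptor genes had a median 0.16 above all genes, with 7 higher and 7 lower (camera adjusted p = 0.0119, adjusted p = 0.606 with an estimated correlation), and 0 passed over the list alone. The call on the inhibitory receptors ended without WT 2 (adjusted p = 0.160) or Ifnar1-SA 3 (0.122), with both of WT 2 and Ifnar1-SA 1 left out (0.155) and with no filter on low values (0.0516). It also ended with a mean TPM of at least 5 (0.0822) and with median-of-ratios (0.0536), TMM (0.0673) or quantile (0.0505) scaling. The median of this list was 0.098 without WT 2, 0.27 without WT 3, 0.25 without Ifnar1-SA 2, 0.081 without Ifnar1-SA 3, 0.082 without the pair, 0.0098 with no filter and 0.0030 with a mean TPM of at least 5, and list means overlapped. Among 20 homing and adhesion receptors (camera adjusted p = 0.672), the inflammatory chemokine receptor Ccr1 rose 3.20-fold from 2.99 ± 1.56 to 9.56 ± 1.77 TPM. The chemokine receptor Cxcr6 rose 3.42-fold from 2.46 ± 1.17 to 8.44 ± 3.17 TPM. Over all genes the limma adjusted p was 0.543 for Ccr1 and 0.825 for Cxcr6, and over the list alone it was 0.0298 for each. For Ccr1 this was 0.0695 without WT 2, 0.0761 without WT 3, 0.0545 without Ifnar1-SA 1, 0.0892 without Ifnar1-SA 2, 0.0588 without Ifnar1-SA 3, and 0.0778, 0.0681 and 0.0749 with median-of-ratios, TMM and quantile scaling. For Cxcr6 it was 0.0765 without WT 2 and otherwise the same as for Ccr1 in these settings. With a replicate block it was 0.0914 for Ccr1 and 0.0680 for Cxcr6, and with WT 2 and Ifnar1-SA 1 left out 0.111 and 0.174. With a model term for that pair it was 0.0740 for Cxcr6.

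The activation and signalling lists did not pass. For the 24 T cell receptor activation genes (camera adjusted p = 0.571), Nr4a2 was at 9.73 ± 0.830 TPM in WT and 7.80 ± 0.913 TPM in Ifnar1-SA and Cd69 at 18.3 ± 7.56 and 11.1 ± 3.28 TPM. For the 25 genes of the interleukin-2 and STAT5 response (camera adjusted p = 0.984), the cytokine gene Lta was at 191 ± 46.1 and 91.2 ± 24.7 TPM and the cell cycle inhibitor Cdkn1a at 1035 ± 156 and 794 ± 24.9 TPM. For the 22 genes of the TGF-beta response (camera adjusted p = 0.0805), the signal transducer Smad3 was at 4.64 ± 0.650 and 3.55 ± 0.702 TPM and Ldlrad4 at 3.30 ± 1.14 and 2.25 ± 0.211 TPM. The TGF-beta list passed as lower without WT 1 (adjusted p = 0.00223), with a mean TPM of at least 5 (0.0249), with median-of-ratios (0.0280) or TMM (0.0320) scaling, with array weights (0.0195) and with a model term for WT 2 and Ifnar1-SA 1 (0.0414). Medians lay below 0 where the test pointed higher for the receptor-proximal, interleukin-2, Th17, homing, fatty acid and neutrophil lists, and the Th2 list had a mean of −0.09 beside a median of 0.08.

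Transcripts of glycolysis and of the amino acid stress response were lower in Ifnar1-SA as lists. All 25 glycolysis genes had a lower mean log2 value, with a median −0.15 relative to all genes (camera adjusted p = 1.6e-04, adjusted p = 0.738 with an estimated correlation), and 0 passed over the list alone. That median was −0.23 without WT 1 and −0.11 at its weakest over the 22 camera settings. The estimated correlation between members was 0.60, so the 25 signs are not independent. The glucose transporters Slc2a3 and Slc2a1 were at 210 ± 95.7 and 158 ± 20.6 TPM in WT and 107 ± 19.0 and 121 ± 13.6 TPM in Ifnar1-SA. All 23 measured genes of amino acid stress and ATF4, the transcription factor of that response, had a lower mean log2 value. The median was −0.32 relative to all genes (camera adjusted p = 6.7e-06, adjusted p = 0.606 with an estimated correlation), and 0 passed over the list alone. It was −0.19 without WT 1 and −0.15 without Ifnar1-SA 3. List means of the genotypes overlapped for both the glycolysis and ATF4 lists. Trib3, a pseudokinase induced by amino acid shortage, was at 42.8 ± 14.3 TPM in WT and 23.5 ± 9.22 TPM in Ifnar1-SA, and Vldlr, a lipoprotein receptor, was at 5.63 ± 2.42 and 2.74 ± 1.12 TPM. The 19 genes of the unfolded protein response did not pass (camera adjusted p = 0.525), with Xbp1 at 241 ± 19.8 and 195 ± 29.2 TPM and Sel1l at 19.0 ± 4.66 and 14.5 ± 3.32 TPM. Nor did the 15 heat shock genes (camera adjusted p = 0.535), with the chaperone genes Dnajb4 at 7.43 ± 1.57 and 5.39 ± 1.26 TPM and Dnajb1 at 26.1 ± 4.08 and 21.8 ± 0.771 TPM.

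Cell cycle and cholesterol synthesis genes were higher in Ifnar1-SA as lists. Of 44 cell cycle and DNA replication genes 38 had a higher mean log2 value, with a median 0.19 above all genes (camera adjusted p = 1.3e-04, adjusted p = 0.817 with an estimated correlation). The microtubule regulator Stmn1 was at 450 ± 108 TPM in WT and 562 ± 72.4 TPM in Ifnar1-SA, and E2f1, a transcription factor of S-phase entry, was at 5.26 ± 0.175 and 6.10 ± 0.605 TPM. The 24 measured cholesterol synthesis genes had a median 0.16 above all genes (camera adjusted p = 0.0318, adjusted p = 0.817 with an estimated correlation). The enzyme gene Hsd17b7 was at 9.04 ± 0.645 TPM in WT and 6.66 ± 0.477 TPM in Ifnar1-SA, and Sc5d at 24.3 ± 2.58 and 29.9 ± 2.24 TPM. In both lists 0 genes passed over the list alone, and list means of the genotypes overlapped. The cell cycle call ended without WT 2 (adjusted p = 0.122) or WT 3 (0.384) and with both of WT 2 and Ifnar1-SA 1 left out (0.449). Its median was 0.38 without WT 1, and 0.10, 0.059 and 0.041 in these settings. The cholesterol call ended without WT 2 (adjusted p = 0.611), WT 3 (0.281), Ifnar1-SA 1 (0.308) or Ifnar1-SA 3 (0.0877) and with WT 2 and Ifnar1-SA 1 left out (0.986). It also ended with a mean TPM of at least 5 (0.0511) and with median-of-ratios (0.0536) or TMM (0.0527) scaling. Its median was 0.25 without WT 1, 0.038 without WT 2, 0.087 without Ifnar1-SA 1 and 0.0057 without the pair. The 32 oxidative phosphorylation genes did not pass (camera adjusted p = 0.320), with Ndufb8 at 476 ± 136 and 572 ± 33.4 TPM and Ndufs3 at 237 ± 26.2 and 213 ± 32.1 TPM. Nor did the 19 genes of fatty acid metabolism (camera adjusted p = 0.437), with Elovl6 at 4.97 ± 1.08 and 3.78 ± 1.10 TPM and Acadl at 83.8 ± 16.8 and 99.1 ± 13.3 TPM. The 29 measured apoptosis and p53 target genes did not pass (camera adjusted p = 0.877), with the death receptor Fas at 27.7 ± 9.65 TPM in WT and 15.6 ± 1.51 TPM in Ifnar1-SA. The oxidative phosphorylation list passed as higher without WT 1 (adjusted p = 0.00223) and as lower without WT 2 (adjusted p = 0.0238).

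**Figure D3:**
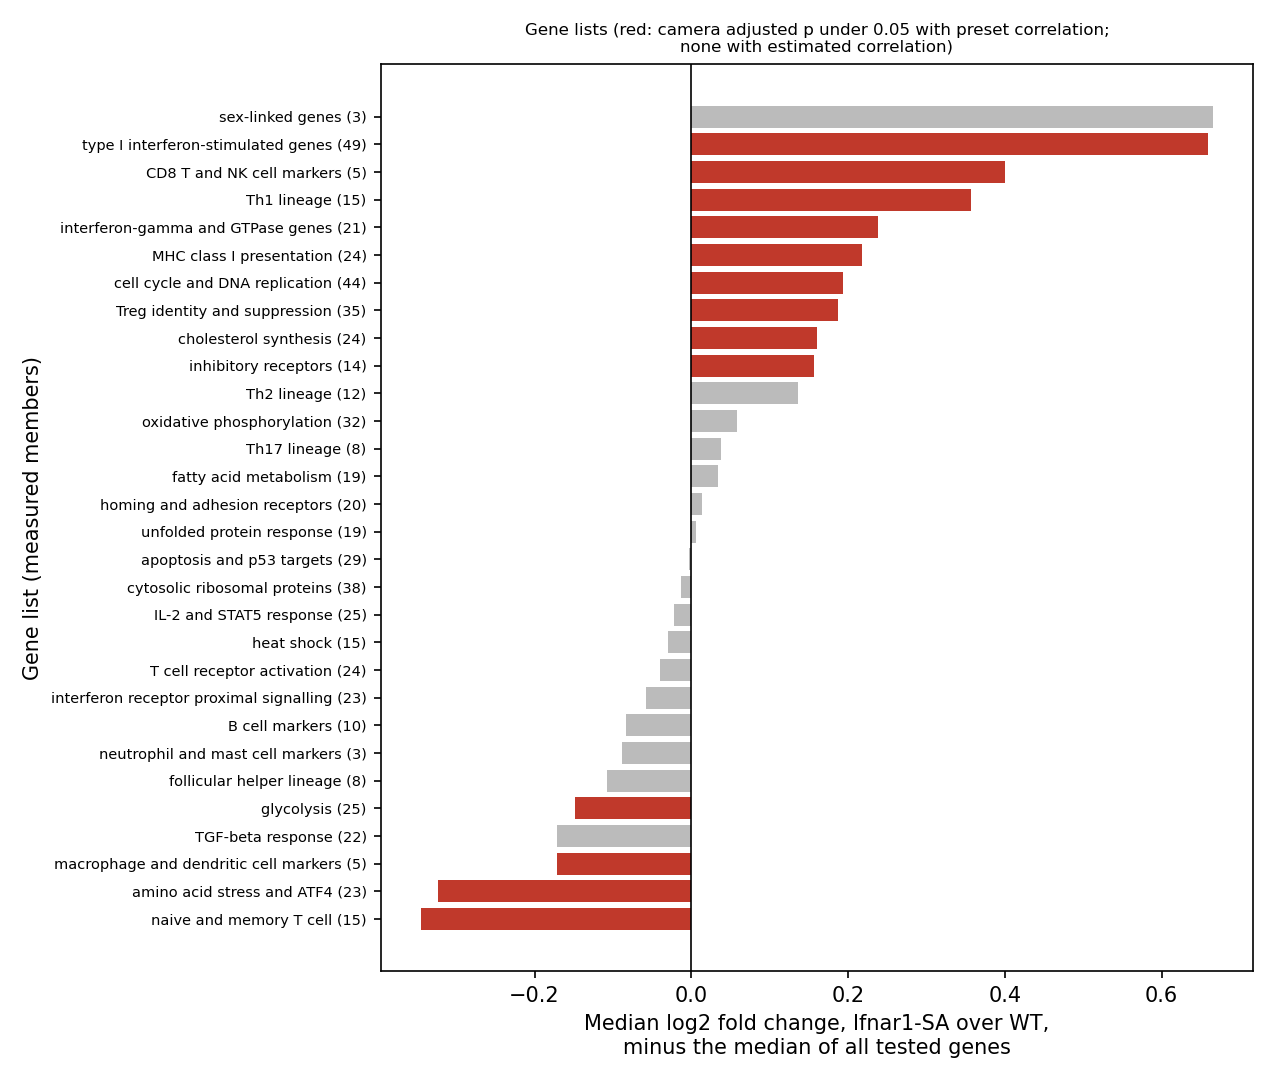
Median log2 fold change, Ifnar1-SA over WT, of each of the 30 tested gene lists minus the median of all genes tested, one bar per list, with the number of measured members in brackets. Red bars mark the 13 lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 pass with an estimated correlation. The type I interferon-stimulated genes lie at 0.66, the 3 measured sex-linked genes at 0.67 and the naive and memory T cell genes at −0.34.

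Gene by gene, 7 genes passed an adjusted p of 0.05 over all 12141 genes tested, 2 higher and 5 lower in Ifnar1-SA, and all 7 were microRNA precursor genes listed at 0 in each library of one genotype. Mir191 (chromosome 9, 108568319 to 108568392, inside 4833445I07Rik) was listed at 0 in WT and was at 18.4, 8.49 and 6.13 TPM in Ifnar1-SA. Mir5110 (chromosome 11, 85760616 to 85760702, inside Bcas3) was listed at 0 in WT and was at 5.76, 7.98 and 11.5 TPM in Ifnar1-SA. The 5 lower genes were listed at 0 in Ifnar1-SA. In the WT libraries Mir8104 (chromosome 10, 122679315 to 122679415, inside Ppm1h) was at 12.6, 12.2 and 20.2 TPM, and Mir378d (chromosome 10, 126710282 to 126710391) at 7.05, 15.2 and 14.5 TPM. Mir148b (chromosome 15, 103285125 to 103285221, inside Copz1) was at 7.57, 5.43 and 3.88 TPM, Mir216a (chromosome 11, 28757012 to 28757083) at 4.27, 6.13 and 4.38 TPM and Mir6379 (chromosome 3, 46900668 to 46900782) at 3.42, 4.91 and 3.51 TPM. The adjusted p-values ran from 0.00445 for Mir8104 to 0.0455 for Mir191. Mir345 was likewise listed at 0 in WT (5.50, 15.3 and 5.51 TPM in Ifnar1-SA, adjusted p = 0.0703), and Mir669n in Ifnar1-SA (13.8, 6.62 and 4.73 TPM in WT, adjusted p = 0.0609). The 7 calls became 0 with WT 2 and Ifnar1-SA 1 left out or with a replicate block, and 1 with a mean TPM of at least 5. They numbered 28 without WT 1, 21 without WT 2, 22 without WT 3, 15 without Ifnar1-SA 1, 19 without Ifnar1-SA 2 and 21 without Ifnar1-SA 3. There were 15 with log2(TPM + 0.1), 14 with log2(TPM + 0.5) and 12 with either robust empirical Bayes or array weights. Median-of-ratios scaling gave 1 higher and 5 lower, and quantile normalization 1 higher and 6 lower.

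Outside the microRNA genes 0 genes passed with limma, the smallest adjusted p being 0.115, and 379 genes in all (175 higher, 204 lower) had an unadjusted p under 0.05 where 607 were expected by chance. That count lay on either side of chance across settings. It was 854 of 12267 genes without WT 1, 242 without WT 2, 219 without WT 3 and 207 without Ifnar1-SA 3. It was 875 with a model term for WT 2 and Ifnar1-SA 1, 1233 with array weights, 658 of 23897 genes with no filter on low values and 224 of 7589 with a mean TPM of at least 5. The genotypes did not overlap for 5.77% of genes (239 higher, 461 lower), against 10% by chance. The median log2 fold change of all genes was −0.06, and TMM scaling moved it by 0.11. Il1r2, the decoy receptor for interleukin-1 (chromosome 1, 40074079 to 40125231), was at 24.2 ± 7.02 TPM in WT and 80.6 ± 8.82 TPM in Ifnar1-SA, 3.34-fold apart (adjusted p = 0.115). Ly6g, known as a neutrophil surface antigen (chromosome 15, 75155240 to 75159126), was at 6.51 ± 0.0492 and 17.0 ± 3.81 TPM (adjusted p = 0.163). Cd24a, a surface glycoprotein gene (chromosome 10, 43578284 to 43584265), was at 55.0 ± 5.61 and 123 ± 16.3 TPM (adjusted p = 0.176). With the small RNA genes left out of the test, an alternative chosen after seeing the data, 2 genes rose and 0 fell of 11354, Il1r2 and Irf7 (adjusted p = 0.0357 for each). That test also gave 2 genes when WT 1, WT 2 and Ifnar1-SA 1 were set against the rest. It gave 2 as well for WT 1, Ifnar1-SA 2 and Ifnar1-SA 3 against the rest. Il1r2 also passed with robust empirical Bayes (adjusted p = 0.0339) and array weights (adjusted p = 0.0475).

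Markers of other cell types ranged from near the floor to abundant. Lyz2, abundant in macrophages, was at most 1.04 TPM in any library. The 10 measured B cell markers did not pass (camera adjusted p = 0.223), though they passed as lower without WT 1 (adjusted p = 0.00587). The most abundant of them, the MHC class II gene H2-Ab1, was at 620 ± 194 TPM in WT and 478 ± 98.4 TPM in Ifnar1-SA (adjusted p = 0.9997). Cd74, an MHC class II chaperone, was at 82.2 ± 30.0 TPM in WT and 50.04 ± 17.4 TPM in Ifnar1-SA, and Ebf1 at 6.49 ± 3.02 and 4.33 ± 0.777 TPM. The 5 measured macrophage and dendritic cell markers were lower as a list (median −0.17 relative to all genes, camera adjusted p = 0.0420, adjusted p = 0.704 with an estimated correlation). Batf3, a transcription factor also made by activated T cells, fell from 371 ± 24.9 to 250 ± 31.8 TPM (limma adjusted p = 0.0430 over the list alone and 0.9997 over all genes). Aif1 was at 1.95 ± 0.785 and 0.930 ± 0.171 TPM. For Batf3 the adjusted p over the list alone was 0.0510 without WT 1, 0.166 without WT 2, 0.0942 without WT 3, 0.102 without Ifnar1-SA 2, 0.281 without Ifnar1-SA 3 and 0.113 with both of WT 2 and Ifnar1-SA 1 left out. It was also 0.168 with no filter on low values, 0.105 and 0.121 with median-of-ratios and TMM scaling, 0.0529 with robust empirical Bayes and 0.0585 with a replicate block. The call on the list ended without WT 2 (adjusted p = 0.148), WT 3 (0.281), Ifnar1-SA 1 (0.298) or Ifnar1-SA 3 (0.112), and with both of WT 2 and Ifnar1-SA 1 left out (0.504) or given a model term (0.0989). It also ended with no filter on low values (0.676), with median-of-ratios (0.0525) or quantile (0.0608) scaling and with a replicate block (0.0595). The list median was −0.36 without WT 1, −0.039 without WT 2, −0.084 without Ifnar1-SA 3 and −0.096 without the pair. It was −0.27 with log2(TPM + 0.1), −0.28 with array weights and −0.022 with no filter on low values, and list means overlapped. The 5 measured CD8 T and NK cell markers were higher as a list (median 0.40 above all genes, camera adjusted p = 0.00617, adjusted p = 0.505 with an estimated correlation). The protease gene Gzma rose 2.53-fold from 33.9 ± 2.35 to 85.8 ± 23.8 TPM (limma adjusted p = 0.00388 over the list alone and 0.353 over all genes). Nkg7 was at 1632 ± 927 and 2161 ± 439 TPM. The call on this list ended without WT 1 (adjusted p = 0.0910) or Ifnar1-SA 3 (0.0955) and with median-of-ratios (0.0536), TMM (0.0673) or quantile (0.0795) scaling. Its median was 0.12 without WT 1, 0.19 without WT 2, 0.24 with array weights and −0.012 with no filter on low values, where camera still pointed higher (adjusted p = 0.0479). The 3 measured neutrophil and mast cell markers did not pass as a list (camera adjusted p = 0.0618). Ly6g passed over that list alone (adjusted p = 6.5e-04), while Csf3r was at 2.80 ± 0.435 and 2.48 ± 0.723 TPM. The neutrophil list passed without WT 3 (adjusted p = 0.0135) or Ifnar1-SA 1 (0.00950), with both WT 2 and Ifnar1-SA 1 left out (0.00770), with log2(TPM + 0.1) (0.0456) and with small RNA genes left out (0.0384). Each of the erythroid and stromal lists had 1 measured member, Epor at 8.92 ± 2.78 and 4.36 ± 0.815 TPM and Pecam1 at 3.58 ± 0.820 and 2.82 ± 0.473 TPM, and was not tested.

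Sex-linked transcripts set 1 library apart. The Y-linked genes Ddx3y and Eif2s3y were at 0.110 and 0 TPM in WT 3, against 2.46 to 5.59 and 10.9 to 23.2 TPM in the other 5 libraries. Xist, transcribed from the inactive X chromosome, was at 3.37 to 8.08 TPM in all 6, so 5 libraries held Xist beside Y-linked transcripts. The WT libraries thus differed among themselves in Y-linked transcripts. The labels do not say whether a library pools several animals. The sex-linked list, with 3 measured members, pools Xist with Y-linked genes, so its test cannot measure sex balance. It had a median 0.67 above all genes and did not pass (camera adjusted p = 0.383). The 38 cytosolic ribosomal protein genes did not pass (camera adjusted p = 0.984), with Rps23 at 2883 ± 270 TPM in WT and 2523 ± 271 TPM in Ifnar1-SA and Rps18 at 5081 ± 844 and 5729 ± 518 TPM. The list passed as higher without WT 3 (adjusted p = 0.0134) and without Ifnar1-SA 1 (adjusted p = 0.0182). WT 2 and Ifnar1-SA 1, 1 library of each genotype, stood apart from the rest. The small RNA gene Rn4.5s was at 3846 and 2978 TPM in them and at 14249 to 20882 TPM in the other 4, and the ribosomal protein gene Rps29 at 3486 and 2619 TPM against 8021 to 9981 TPM. The microRNA gene Mir6236 alone took 6.52% to 11.9% of the TPM of a library. None of the 13 mitochondrially encoded genes had a row in the table used, so their share was not analysed here.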

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

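The tests with small RNA genes left out and with WT 2 and Ifnar1-SA 1 given a model term or left out were chosen after the results were seen. The interferon-stimulated and Treg lists were higher in Ifnar1-SA and past the threshold in 22 of 22 camera settings, with adjusted p at most 5.5e-22 and 0.0172. They lost the call with an estimated correlation (adjusted p 0.505 and 0.606) and with fry (0.485 and 0.811). All 22 settings shared the preset inter-gene correlation of 0.01. The correlation estimated from the data was 0.52 for the interferon-stimulated list and 0.11 for the Treg list, so the adjusted p at the preset value overstates the evidence. Fry does not compare the same quantity as camera. The interferon-gamma, MHC class I, naive and memory, glycolysis and ATF4 lists also passed in 22 of 22 camera settings and lost the call with an estimated correlation (adjusted p 0.606, 0.606, 0.606, 0.738 and 0.606). TPM without read depth limits all low genes, and the causes of the changes below were not tested except where fewer libraries or genes were fitted.

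The 7 genes past the threshold (2 higher, 5 lower) numbered 15 (12 lower) with log2(TPM + 0.1) and 14 (11 lower) with log2(TPM + 0.5), with 3 higher in both. With no filter on low values 1 was higher, and with a mean TPM of at least 5 there was 1 in all, 0 higher and 1 lower. Median-of-ratios, TMM and quantile scaling each left 1 higher. Robust empirical Bayes gave 12 (4 higher, 8 lower) and array weights 12 (9 lower). With small RNA genes left out there were 2 (0 lower), with the term for WT 2 and Ifnar1-SA 1 there was 1 higher, and leaving out both libraries gave 0 (0 higher, 0 lower) with limma, with 366 genes at an unadjusted p under 0.05. Leaving out 1 library gave 15 to 28 genes, 2 to 10 higher and 8 to 26 lower.

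Labels share replicate numbers between the genotypes, so a replicate block was fitted as an alternative. Deviations of same-numbered libraries correlated at −0.11, −0.11 and 0.15. Not every library correlated best with its own number (WT 1 with Ifnar1-SA 2, WT 2 with Ifnar1-SA 1, WT 3 with Ifnar1-SA 3). With deviations taken from a mean of 3 libraries per genotype, these correlations cannot decide whether equal numbers mark a shared animal, litter or day. The block gave 0 genes (0 higher, 0 lower) with limma, with 399 at an unadjusted p under 0.05, and 7 interferon-stimulated genes adjusted over the list alone. In it the receptor-proximal list (adjusted p 0.920) and apoptosis list (0.984) turned direction, both far from the threshold.

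Other lists that turned direction had the following adjusted p. With fry they were the receptor-proximal (0.890), interleukin-2 (0.811), homing (0.988) and fatty acid (0.988) lists. With no filter the ribosomal list (0.676) turned, and with a mean of at least 5 TPM the receptor-proximal (0.986), interleukin-2 (0.818) and follicular helper (0.818) lists. Median-of-ratios and TMM scaling turned the interleukin-2 (0.973 and 0.948) and ribosomal (0.655 and 0.711) lists, and quantile normalization the receptor-proximal (0.666), interleukin-2 (0.456) and oxidative phosphorylation (0.615) lists. The ribosomal list turned with no intensity trend (0.956) and with small RNA genes left out (0.951). Array weights turned the receptor-proximal (0.760), interleukin-2 (0.779) and homing (0.787) lists. The receptor-proximal list also turned with ribosomal protein genes left out (0.968) and with the term for WT 2 and Ifnar1-SA 1 (0.870). Leaving out that pair turned the receptor-proximal (0.877), interleukin-2 (0.931), oxidative phosphorylation (0.504), fatty acid (0.736) and ribosomal (0.569) lists.

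Some lists turned direction without 1 library, and over the 6 such settings their adjusted p ranged as follows: receptor-proximal 0.369 to 0.879, interleukin-2 0.437 to 0.872, Th17 0.104 to 0.964, homing 0.349 to 0.873, unfolded protein response 0.104 to 0.903, oxidative phosphorylation 0.00223 to 0.749, apoptosis 0.294 to 0.873, heat shock 0.230 to 0.990, ribosomal 0.0134 to 0.534, B cell 0.00587 to 0.990, fatty acid 0.155 to 0.990 and Th2 0.104 to 0.833. The 5 following genes turned sign in log2 fold change, none past the threshold. Ifnb1 was at 0.036 with median-of-ratios, 0.045 with TMM and 0.077 with quantile scaling, and at −0.25 to 0.16 without 1 library. Csf3r was at 0.027 with array weights, 0.13 with the pair left out and −0.27 to 0.036 without 1 library. Gata3 was at −0.026, −0.024 and −0.023 to 0.10 in the same settings, Tbx21 at −0.010 with the pair left out, and Eif2s3y at −0.068 to 2.02 without 1 library.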

Other observations

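The tests of fragment steps, of microRNA detection, of scaling and of other cells were chosen after the results were seen. Beyond the gene lists, several genes had non-overlapping libraries without passing over all genes, and these were chosen after their values were seen. Pdpn, which encodes the surface glycoprotein podoplanin, was at 7.36 ± 1.18 TPM in WT and 17.9 ± 2.64 TPM in Ifnar1-SA (mean ± SD, n = 3; limma adjusted p = 0.188). Cyp11a1, the enzyme that starts steroid hormone synthesis, was at 113 ± 33.7 and 243 ± 42.8 TPM (adjusted p = 0.843). Trat1, an adaptor of the T cell receptor, was at 24.8 ± 4.05 and 9.75 ± 1.64 TPM (adjusted p = 0.177, and 0.0368 with quantile normalization), and Nrn1, the gene of neuritin, at 54.5 ± 17.3 and 17.9 ± 3.47 TPM (adjusted p = 0.388). Erdr1 was at 136 ± 21.9 and 43.7 ± 20.9 TPM (adjusted p = 0.543).

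The genotypes overlapped in the following genes, in which WT 1 had the highest or lowest value of the WT libraries (adjusted p = 0.9997 for each). The protease gene Gzmb was at 1165, 437 and 596 TPM in the WT libraries and 746, 1619 and 1595 TPM in the Ifnar1-SA libraries, and the chemokine gene Ccl4 at 4511, 730 and 2209 TPM and 2551, 5868 and 8010 TPM. The inhibitory receptor genes Havcr2 (11.997, 3.85 and 3.54 TPM in WT against 9.56, 14.0 and 12.6 TPM) and Pdcd1 (61.3, 33.3 and 26.4 TPM against 69.5, 56.7 and 54.7 TPM) were likewise highest in WT 1, and Ccr7, a homing receptor of naive T cells, was lowest there (91.8, 305 and 252 TPM against 138, 50.9 and 78.0 TPM).

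The 7 genes past the threshold were all microRNA precursor genes listed at 0 in one whole genotype. A candidate explanation is that each value rests on a few fragments of a very short transcript. In 6 of the 7 genes, all but Mir8104, the values stood in whole-number ratios, within 1%, after division by a relative step per library shared by microRNA genes. The smallest such numbers add to 3 to 9 fragments, a lower bound, since the unit of each gene was left free. The rule was met by 3.2% of random value triples and by 72.3% of 415 microRNA genes above 0 in at least 3 libraries, so it marks the class more than the 7. Whether detection of microRNA precursors shifted more widely with the genotype stays open. Of 121 microRNA genes above 0 in exactly 3 libraries, 12 were above 0 in WT alone and 3 in Ifnar1-SA alone. Independent detection at each library's own rate gave 12.5 and 1.98 (binomial p = 0.888 for 15 in all against 14.4). These rates were fitted to the same genes, so a shift of a whole genotype would be taken up in the expected numbers. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Of the 10, 6 gave at least the 7 genes of the real split, the highest other 14. The genotype split thus did not stand out from other groupings of the libraries in its number of calls.

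The splits that set WT 1, WT 2 and Ifnar1-SA 1, or WT 1, Ifnar1-SA 2 and Ifnar1-SA 3, against the rest had 2781 and 2084 genes at an unadjusted p under 0.05 against 379 for the genotype (854 without WT 1, 242 without WT 2, 219 without WT 3, 207 without Ifnar1-SA 3, 875 with a term for the pair, 1233 with array weights). The remaining splits had 111 to 558, on either side of the genotype. The 2 high counts point to a structure of the samples other than the genotype, which was not tested.

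Interferon-stimulated genes were higher in Ifnar1-SA although type I interferon transcripts were near the floor in both genotypes. The tables argue against scaling as the whole cause, since the list's own median was 0.60 and at its lowest 0.65 under 3 other scalings, which moved that of all genes by up to 0.11. The pair WT 2 and Ifnar1-SA 1 holds 1 library of each genotype, so a difference that both share cancels between the genotypes by design. With both left out the list's median was 0.68 above all genes. The tables argue against myeloid or B cells, since 11 of their markers changed by −0.649 TPM in sum (6.81 ± 2.17 and 6.16 ± 1.90 TPM) while Bst2 gained 271 TPM. CD8 T, NK, neutrophil or mast cells stay open although the cultures began from naive CD4 T cells. Of 8 measured markers 4 were higher in mean log2 value, a share that decides neither way. Gzma and Ly6g passed the threshold over their lists alone. The 16 neutrophil and mast cell markers, 3 of them at a mean of at least 1 TPM, summed to 14.6 TPM in WT and 23.5 TPM in Ifnar1-SA. Ly6g alone held 6.51 and 17.0 TPM of these sums. The 16 CD8 T and NK cell markers summed to 1708 and 2291 TPM. The genotype stays open as untested. The splits are too few for a share under 0.05, with 0.66 for the real split, the 1 of 10 that gave as much, and 0.47 for the highest other.

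For the Treg list the real value was 0.19 and the highest other 0.10, with 1 of 10 splits as large, too few splits for a share under 0.05.

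A further hypothesis was that DNA of another mouse strain near the altered Ifnar1 allele could change neighbouring genes. Within 10 Mb of Ifnar1, 0 of 58 tested genes had an unadjusted p under 0.05, against 3.13% of 11844 other genes (two-sided Fisher's exact p = 0.265), so no excess was seen and the number of genes is too small to exclude one.

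Cells labelled as Treg carried little Foxp3 mRNA beside abundant Th2 cytokine mRNA. Foxp3 was at most 1.82 TPM in any library, while Il4 was at least 230 TPM and Il24 at least 1114 TPM. At the level of Foxp3 mRNA these values do not bear out the Treg label, which was kept as given. Mx2, a classical interferon target under the expression filter, was at 0.173, 0.325 and 0.324 TPM in WT and 1.87, 0.8001 and 2.45 TPM in Ifnar1-SA, and Rtp4 at 0.114, 0.308 and 0.220 TPM against 0.475, 0.254 and 1.63 TPM.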
